A study of Mus musculus with 6 samples.

How the data were processed

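RNA sequencing of sorted lung alveolar macrophages compared 3 untreated Car4fl/fl mice with 3 untreated Car4fl/fl-CD11cCre mice, 1 library each. Per the labels' protocols, RNA was isolated with the RNeasy Plus Micro kit and polyadenylated mRNA was captured for the libraries. The authors deposited a table of whole-number counts per gene, without normalization. The submitters' processing notes name cutadapt 2.5, STAR 2.6.1, featureCounts 1.6.4, Picard 2.21.1, SAMtools 1.9, StringTie 2.0, FastQC 0.11.8, bcl2fastq 2.20.0.422, edgeR 3.26.5 and DESeq2 1.22.1 and the build GRCm38, without a role or an order for each. The annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Counts of near-identical copies, such as Ear6, Rnase2a, Chil3, Lyz2, Hbb-bs, Ftl1, the immunoglobulin genes and the ribosomal protein genes, are uncertain.

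The table held 46078 gene rows. Of their identifiers 45229 were found in GENCODE M21, an annotation of GRCm38 used here for coordinates, and 849 were not. The symbol was the same in both for 41740, and 214 symbols occurred on more than 1 row, where the row with the most counts stood for the symbol. Columns were assigned to mice through the library names in the labels. Totals lay between 53824475 and 65443314 counts per library, mitochondrial transcripts made up 1.08 to 1.17% and the 10 most abundant genes 7.97 to 10.02% of the counts. Floors of 3 counts cover counting error only, and PCR copies are not separate molecules. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom between 21.9 and 57.5.

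The counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group and its minimum count of 10 (15147 genes left), TMM factors (0.986 to 1.015), estimateDisp, glmQLFit with its default settings and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The biological coefficient of variation was 14.4% and the prior degrees of freedom 3.79. Standard errors were obtained as the absolute log2 fold change divided by the square root of the F statistic. The design had no covariate and no block, and was fixed before the data were examined, as were the alternatives and 46 gene lists, of which 30 were functional, 13 held markers of other cell types and the others were loci and sex-linked genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with an estimated correlation, and with fry. Members were also adjusted over the list alone.

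The genes named were Car4, then, among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, the 12 of largest log2 fold change in each direction, leaving out predicted genes, antigen receptor segments and pseudogenes. With fewer than 10 genes past the threshold on a side, as here, the 10 of smallest p on that side were named by the same exclusions. Each list added up to 4 members past the threshold over all genes, or with fewer than 2 such members its 2 most abundant tested members, given with values. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen. The same code was tested on counts simulated for 15147 genes, of which 50 changed by each fold: edgeR recovered 60% at a fold of 1.5, 88% at 2, 96% at 4 and 98% at 8, with 12 false calls among 183, and made 1 call with nothing changed. DESeq2 recovered 68, 94, 96 and 98% with 38 false calls among 216. The simulation used the dispersions estimated here, gave all Cre libraries the same fold and changed only genes with a mean of at least 1 CPM. It therefore does not measure recovery of genes whose change differs between the Cre libraries.

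Alternatives were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma-voom with and without sample weights, no filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, leaving out each library, adjusted p of 0.01 and 0.1, glmTreat against a fold of 1.5, and leaving out genes of other cell types. After seeing the data the robust and the newer settings of glmQLFit were added. A term for sex was not fitted because all libraries were of 1 sex. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.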

Results

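Polyadenylated RNA was sequenced from alveolar macrophages, the resident macrophages of the airspaces, sorted from the lungs of untreated mice. Car4fl/fl mice carried loxP-flanked alleles of Car4, which encodes the membrane-anchored carbonic anhydrase 4, and served as controls (3 mice). Car4fl/fl-CD11cCre mice carried the same alleles and a Cre recombinase driven by CD11c, the integrin encoded by Itgax (3 mice). The libraries held between 53824475 and 65443314 counts in genes. Values are TMM-normalised CPM, counts scaled to library size, as mean ± SD of 3 libraries per group with the control first. At these depths 3 counts correspond to 0.0465 to 0.0557 CPM. A positive log2 fold change means a higher value in the Cre libraries, and 15147 genes were tested. The comparison asks which transcripts of alveolar macrophages differ once Car4 is deleted in CD11c-expressing cells. No group carried the Cre with unfloxed Car4, so an effect of the Cre transgene cannot be told apart from deletion of Car4.

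Car4 transcript fell to 10.7% of its control mean over the 3 Cre libraries and was lower in every Cre library than in any control. The control libraries held 499, 385 and 270 CPM and the Cre libraries 40.2, 46.9 and 36.3 CPM. The fall was 9.36-fold, with a log2 fold change of -3.23 ± 0.22 (SE) and an adjusted p of 0.0047 (edgeR quasi-likelihood, Benjamini-Hochberg). Car4 (ENSMUSG00000000805) lies on chromosome 11 of GRCm38 from 84957786 to 84966044 on the plus strand and has 10 exon blocks in the annotation. Which exons are flanked by loxP sites is not given in the sources used here, and reads from exons outside that part may persist after deletion. The call was lost without control replicate 2 (log2 fold change -3.23, adjusted p 0.0549 in edgeR) and with robust dispersions, chosen after seeing the data (adjusted p 0.0719), against a range of 2.49e-28 to 0.0719 over the alternatives.

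Plcb4, which encodes the phosphoinositide-cleaving enzyme phospholipase C beta 4, was the only gene called higher by edgeR. It was low in control macrophages, at 0.542 ± 0.00854 CPM and rose to 27.9 ± 0.94 CPM. Its log2 fold change was 5.68 ± 0.09 (SE), with an adjusted p of 1.17e-07 (edgeR quasi-likelihood, Benjamini-Hochberg). Plcb4 (ENSMUSG00000039943) lies on chromosome 2 from 135659011 to 136014593 on the plus strand. Car4 was the only gene called lower, so edgeR gave 1 gene in each direction.

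At an unadjusted p under 0.05, 990 genes were higher and 951 lower in the Cre libraries, where 757 in all would be reached by chance. The 3 values of each group did not overlap for 17.9% of the tested genes, against 10% by chance for 3 libraries against 3. DESeq2 called 393 genes higher and 237 lower, edgeR without a filter on low counts 340 and 183. The Cre libraries were unlike each other: on the first principal component, which held 47% of the variance, Cre library 1 was at 0.4 and Cre libraries 2 and 3 at 39.8 and 39.4, with the controls between -29.7 and -22.5. The count depended on single libraries, since edgeR called 249 genes higher and 37 lower without Cre replicate 1. It called 15 and 52 without control replicate 3, 8 and 1 without Cre replicate 2, and 1 and 0 without control replicate 2.

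**Figure D1:**
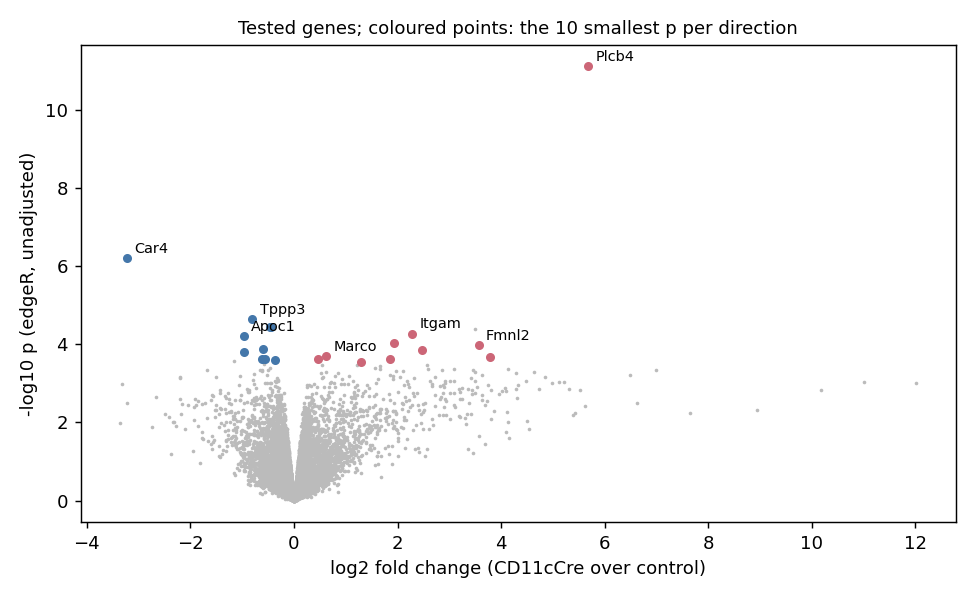
Log2 fold change of Cre over control libraries (x axis) against −log10 of the unadjusted edgeR p (y axis) for each of the 15147 tested genes, where coloured points are the 10 genes of smallest p in each direction under the naming rule. Plcb4 at 5.68 and Car4 at -3.23 are the genes past an adjusted p of 0.05.

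Itgam, Marco, Thbd and Msr1, which encode surface receptors, were among the 10 genes of smallest p on the higher side. Next to Plcb4 these were Itgam, Sestd1, Fmnl2, Slc30a4, Marco, Cpq, Kcnj15, Thbd and Msr1, and these had adjusted p between 0.116 and 0.146 (edgeR quasi-likelihood, Benjamini-Hochberg), so none passed. DESeq2 called each of these genes (adjusted p 4.79e-13 to 0.000278), as did edgeR without a filter on low counts (adjusted p 0.000173 to 0.0037). By limma-voom and glmTreat none of these genes was called, and in the simulation DESeq2 made 38 false calls among 216. For each of them the 3 Cre values lay above the 3 control values. Itgam, the CD11b integrin chain of the complement receptor 3, was at 5.42 ± 1.5 against 26.4 ± 8.33 CPM, a log2 fold change of 2.28 ± 0.29 (SE). The scavenger receptors Marco and Msr1 were at 296 ± 15.5 against 455 ± 57 CPM and at 22.2 ± 4.01 against 54.4 ± 14.7 CPM. Thbd, thrombomodulin, was at 95.7 ± 7.95 against 132 ± 7.19 CPM. The zinc transporter gene Slc30a4 was at 1.63 ± 0.395 against 9.07 ± 3.96 CPM and the potassium channel gene Kcnj15 at 1.02 ± 0.341 against 3.66 ± 0.791 CPM. The formin gene Fmnl2 was at 0.677 ± 0.0627 against 8.06 ± 4.96 CPM, Sestd1 at 2.3 ± 0.229 against 8.74 ± 3.07 CPM and the carboxypeptidase gene Cpq at 0.141 ± 0.0226 against 1.98 ± 1.17 CPM, with log2 fold changes of 3.57, 1.93 and 3.79. Of these 10 genes, Plcb4, Sestd1, Fmnl2, Slc30a4 and Thbd lie on chromosome 2.

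On the lower side the genes after Car4 were Tppp3, Galnt3, Tnfrsf12a, Apoc1, Naprt, Mgst3, Cbfa2t3, Hivep3 and Plk3, with adjusted p between 0.104 and 0.146 (edgeR quasi-likelihood, Benjamini-Hochberg). Their log2 fold changes lay between -0.96 and -0.36, and for each of them the 3 Cre values lay below the 3 control values. DESeq2 called each of these genes (adjusted p 2.09e-13 to 3.83e-05), as did edgeR without a filter on low counts (adjusted p 0.000419 to 0.00973). By limma-voom and glmTreat none of these genes was called. Tppp3, a tubulin polymerisation gene, was at 329 ± 21 against 189 ± 21.2 CPM, and the apolipoprotein gene Apoc1 at 5.34 ± 0.406 against 2.74 ± 0.135 CPM. Mgst3, a microsomal glutathione transferase, was at 88.4 ± 18.7 against 45.4 ± 1.62 CPM. Naprt, which makes nicotinate mononucleotide in NAD synthesis, was at 16 ± 0.608 against 10.6 ± 0.869 CPM, and the glycosyltransferase gene Galnt3 at 137 ± 4.76 against 100.1 ± 3.91 CPM. Tnfrsf12a, the TWEAK receptor, was at 34.7 ± 1.41 against 25.1 ± 0.61 CPM and the kinase gene Plk3 at 271 ± 3.06 against 211 ± 12.5 CPM. The transcriptional regulators Cbfa2t3 and Hivep3 were at 25.6 ± 2.12 against 17.4 ± 1.35 CPM and at 168 ± 17.6 against 109 ± 11.2 CPM.

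**Figure D2:**
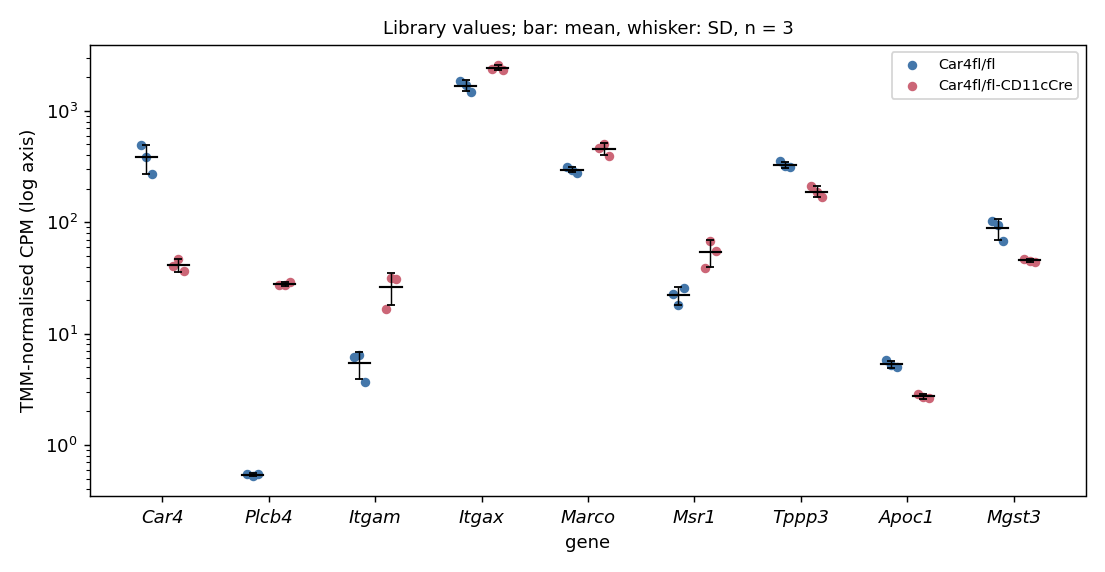
TMM-normalised CPM on a log axis for 9 genes (x axis), with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3) for Car4fl/fl in blue and Car4fl/fl-CD11cCre in red. Car4 lies between 270 and 499 CPM in the controls and between 36.3 and 46.9 CPM in the Cre libraries.

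Of 46 fixed lists, 44 had at least 5 tested members, and camera at its preset inter-gene correlation of 0.01 called 17 of them, 15 higher and 2 lower. With the correlation estimated from these 6 libraries camera called none, and the smallest adjusted p was 0.505. The rotation test fry asks whether a list's genes move one way on balance, and called none either, with a smallest adjusted p of 0.317. Its mixed form, which asks for change in either direction, called 16. Of the lists called by camera these held interferon-stimulated genes, phagocytosis, and complement and coagulation. The others were alveolar macrophage identity, carbonic anhydrases, acid-base transport, surfactant and lipid handling, fatty acid synthesis, mitochondrial mRNAs and p53 targets. They also held GM-CSF, TGF-beta and IL-13 genes, Itgax neighbours, and markers of classical monocytes, alveolar type 2 cells, airway epithelium and dendritic cells. None of the 791 tested members of the functional lists passed edgeR over all genes, against 2 of 14356 other genes. With 2 calls, 1 of them Car4, which no list holds, the planned Fisher's exact test could not fall under 0.05, and it is not used. Of these members 205 had an unadjusted edgeR p under 0.05 and DESeq2 called 90. Camera values are Benjamini-Hochberg adjusted over the 44 lists. List members given beyond those of the naming rule were chosen after their values were seen.

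Genes of cholesterol synthesis were higher together in the Cre libraries. All 25 tested members were above control, with a median log2 fold change of 0.44. In edgeR 22 passed adjusted over the list alone and 0 over all genes, against 22 higher and 0 lower at an unadjusted p under 0.05, and 17 and 0 by DESeq2. Camera gave an adjusted p of 3.23e-26 at the preset correlation and an adjusted p of 0.505 with an estimated correlation. The squalene epoxidase gene Sqle was at 55 ± 4.6 against 85.9 ± 19.6 CPM and the isomerase gene Idi1 at 9.19 ± 0.543 against 14.2 ± 1.86 CPM. Srebf2, which encodes the transcription factor of the pathway, was at 181 ± 8.86 against 215 ± 16.8 CPM. The 3 Cre libraries had list medians of 0.32, 0.63 and 0.38 over the control mean. Other lipid lists were not called by camera: fatty acid synthesis had an adjusted p of 0.166, fatty acid oxidation 0.389, and surfactant and lipid handling 0.712. The mixed form of fry called fatty acid synthesis (adjusted p 0.0286) and surfactant and lipid handling (0.0314), and not fatty acid oxidation (0.0605). Within these lists Acly was at 460.2 ± 31.4 against 521 ± 33.4 CPM and Elovl5 at 190.2 ± 2.61 against 183 ± 9.3 CPM. Cpt1a was at 615 ± 10.6 against 578 ± 51 CPM, and Lpl at 3875 ± 841 against 2988 ± 214 CPM and Abcg1 at 2722 ± 158 against 2409.9 ± 315 CPM. Adjusted over the list alone, the fatty acid synthesis genes Fasn and Fads2 were higher and the oxidation gene Pdk4 lower. Of surfactant and lipid handling Cd36, Msr1 and Acsl3 were higher and Apoc1 and Mylip lower by the same adjustment.

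Complement genes, profibrotic genes and markers of interstitial macrophages were higher in the Cre libraries, by amounts that differed between these libraries. Of the complement and coagulation list 15 of 18 tested members were above control and 9 passed over the list alone, with an adjusted p of 3.92e-11 by camera and an adjusted p of 0.505 with an estimated correlation. C1qa, a chain of the complement initiator C1q, was at 0.68, 1.01, 0.72 CPM in the controls and at 1.88, 12.4, 18.2 CPM in the Cre libraries. The most abundant members, Itgb2 and F7, were at 2469 ± 67 against 2599 ± 277 CPM and at 569.9 ± 37.7 against 533 ± 1.58 CPM. Of the profibrotic and monocyte-derived list 20 of 28 were above control and 14 passed over the list alone (camera adjusted p 2.84e-09, and adjusted p 0.505 with an estimated correlation). The macrophage elastase gene Mmp12 was at 7.97, 4.85, 4.84 CPM in the controls and 23.9, 111, 566 CPM in the Cre libraries. The abundant members Cd9 and Fn1 were at 3428 ± 392 against 2998 ± 155 CPM and at 2618 ± 115 against 2282 ± 346 CPM. Interstitial macrophage markers had 16 of 19 members above control, 7 higher and 1, Cd163, lower over the list alone, with camera adjusted p 1.51e-06 and adjusted p 0.505 with an estimated correlation. Of these 19 markers 11 belonged to another list too, and 6 reached 1 CPM in each control library. Their medians over the control mean were 0.26, 0.91 and 1.28 in Cre libraries 1, 2 and 3, against 0.09, 0.56 and 0.46 for the complement list and 0.11, 0.97 and 0.45 for the profibrotic list. Apoe was at 95.5 ± 9.78 against 284 ± 206 CPM and Cd81 at 175 ± 7.97 against 194 ± 28.1 CPM.

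**Figure D3:**
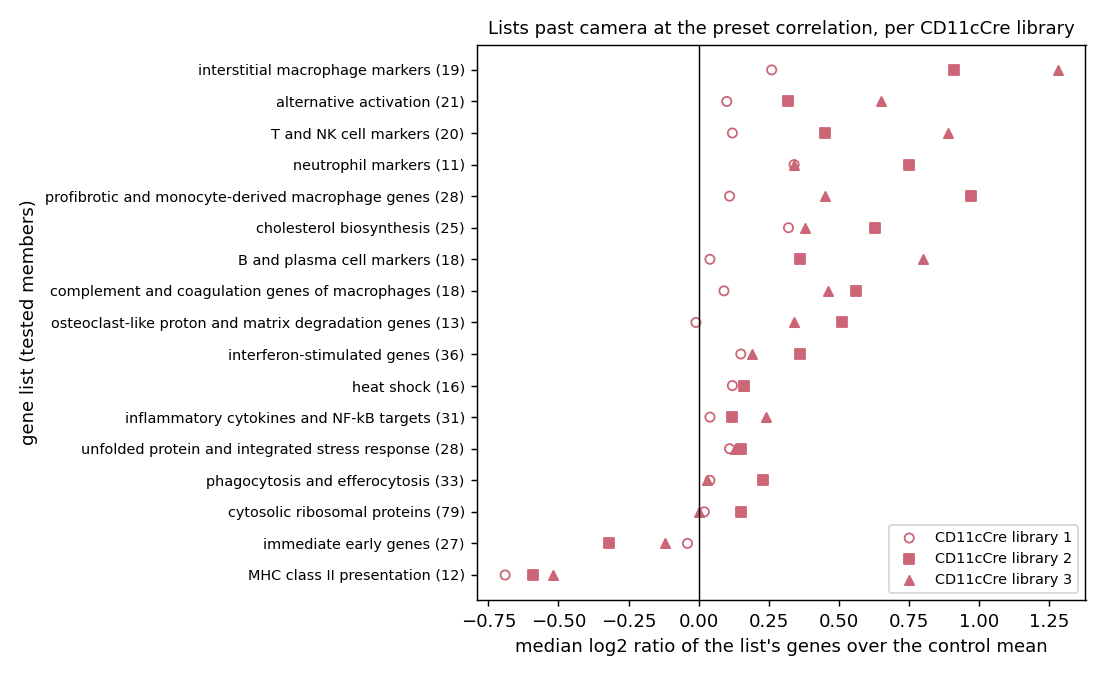
Median log2 ratio over the control mean (x axis) of the members of each of the 17 lists called by camera (y axis, tested members in brackets), with 1 symbol for each Cre library. Interstitial macrophage markers range from 0.26 in Cre library 1 to 1.28 in Cre library 3, and MHC class II genes lie between -0.69 and -0.52.

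Alternative activation genes were higher on balance but not uniformly. Of the list, 15 of 21 tested members were above control, 7 higher and 2 lower over the list alone, with camera adjusted p 0.000325 and adjusted p 0.506 with an estimated correlation. The arginase gene Arg1 was at 0.48, 0.95, 1.6 CPM in the controls and 8.16, 72.2, 192 CPM in the Cre libraries. The chitinase-like gene Chil3 was at 15628 ± 1912 against 26611 ± 7111 CPM and the mannose receptor gene Mrc1 at 2487 ± 17.1 against 2643 ± 23.8 CPM. Phagocytosis and efferocytosis genes had 22 of 33 members above control, 6 of them past the list alone (camera adjusted p 3.46e-05, and adjusted p 0.506 with an estimated correlation), with their most abundant member Lyz2 at 18271 ± 3514 against 15521 ± 2719.7 CPM. The osteoclast-like list had 11 of 13 above control and 3 (Dcstamp, Mmp9 and Mmp12) past the list alone, with camera adjusted p 0.000941 and adjusted p 0.506 with an estimated correlation. The call of the osteoclast-like proton and matrix degradation genes was lost under the stricter filter (camera adjusted p 0.114, against 7.91e-08 to 0.114 over the alternatives at the preset correlation). Its abundant members Atp6v0d2 and Ctsk were at 1139.8 ± 78.9 against 1289 ± 76.4 CPM and at 535 ± 128 against 623 ± 169 CPM. Cre library medians were 0.10, 0.32 and 0.65 for alternative activation, 0.04, 0.23 and 0.03 for phagocytosis and -0.01, 0.51 and 0.34 for the osteoclast-like list. The list of alveolar macrophage identity was not called by camera (adjusted p 0.35), with 17 of 43 members above control and 6 higher and 2 lower over the list alone. Siglecf was among the lower ones, and Marco, Chil3, Fabp5, Ear6 and Itgax were among the higher ones. The mixed form of fry, which allows both directions, called this list (adjusted p 0.0303). The receptors and targets of GM-CSF, TGF-beta and IL-13 had an adjusted p of 0.847 by camera, with Runx3 higher over the list alone. Its median was -0.007 while its mean and camera direction were positive, and the abundant Csf2rb was at 782 ± 12.2 against 747 ± 27.6 CPM and Tgfbr2 at 695 ± 23.6 against 746 ± 48.4 CPM.

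MHC class II genes, which present extracellular antigen to T cells, were lower in the Cre libraries. Of 12 tested members 11 were below control and 8 passed over the list alone, with a median log2 fold change of -0.61, a camera adjusted p of 8.52e-07, and an adjusted p of 0.506 with an estimated correlation. The mean difference of the list was -0.90 between the genotypes and 1.09 in size in another split of the 6 libraries (exact permutation p 0.2). Control library 3 was itself low: Cd74, the invariant chain, was at 1297, 777, 153 CPM in the controls and 105, 101, 190.1 CPM in the Cre libraries. H2-Aa was at 336, 201, 35.8 CPM and 27.9, 31.6, 54.5 CPM in the same order, whereas the values of H2-DMa did not overlap between groups, at 319 ± 40.5 against 249.8 ± 15.2 CPM. Interferon-stimulated genes were higher for 33 of 36 members, with Oas1g, Oas2, Oas3, Oasl2 and Slfn5 past the list alone, camera adjusted p 1.63e-08 and adjusted p 0.505 with an estimated correlation. Their median log2 fold change was 0.18, and the abundant members Parp14 and Trim30a were at 88.2 ± 6.03 against 97.5 ± 0.31 CPM and at 65.7 ± 1.74 against 67.8 ± 0.149 CPM. Inflammatory cytokines and NF-kB targets were above control for 19 of 31 members, with Ccl9, Ptgs2, Sod2 and Traf1 higher and Tnf lower over the list alone, camera adjusted p 0.0411 and adjusted p 0.506 with an estimated correlation. This call was lost without control replicate 2 (0.0651), Cre replicate 2 (0.0708) or Cre replicate 3 (0.252), as adjusted p of camera, and with the stricter filter (0.501), against 2.02e-05 to 0.501 over the alternatives at the preset correlation. Tnfaip2 was at 1095 ± 115 against 945 ± 60 CPM and Nlrp3 at 227 ± 10.2 against 189 ± 42.6 CPM.

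Heat shock genes were higher for 14 of 16 members (camera adjusted p 6.52e-05, and adjusted p 0.506 with an estimated correlation). Over the list alone edgeR passed 0, against 6 higher and 0 lower at an unadjusted p under 0.05, and 2 and 0 by DESeq2. The abundant Hsp90ab1 was at 1620.4 ± 56.9 against 1734 ± 41.6 CPM and Hspa8 at 862 ± 127 against 1076 ± 39.1 CPM. Genes of the unfolded protein and integrated stress response were higher for 23 of 28 members (camera adjusted p 0.000325, and adjusted p 0.506 with an estimated correlation). Over the list alone edgeR passed 0, against 8 higher and 2 lower at an unadjusted p under 0.05, and 3 and 1 by DESeq2. The chaperone genes Calr and Hspa5 were at 1335 ± 103 against 1499 ± 65.7 CPM and at 1172 ± 138 against 1426 ± 161 CPM. Immediate early genes were lower for 19 of 27 members with Egr2, Ier2, Ier5 and Maff past the list alone, camera adjusted p 0.00424 and adjusted p 0.534 with an estimated correlation. That call was lost without control replicate 3 (camera adjusted p 0.13) or Cre replicate 2 (0.17), against 0.000117 to 0.17 over the alternatives at the preset correlation. Fos was at 1715 ± 330.4 against 1622 ± 309 CPM and Junb at 1293 ± 72.1 against 1154 ± 36.6 CPM. Cytosolic ribosomal protein genes had 69 of 79 members above control (camera adjusted p 0.00906, and adjusted p 0.909 with an estimated correlation). Over the list alone edgeR passed 0, against 0 higher and 0 lower at an unadjusted p under 0.05, and 0 and 0 by DESeq2. The list had a median log2 fold change of 0.06. It was lost without Cre replicate 1 (adjusted p 0.0572) and its direction turned without control replicate 2 (0.808) or Cre replicate 2 (0.969), all by camera, against 5.07e-08 to 0.969 over the alternatives at the preset correlation. Rplp0 was at 943 ± 75.6 against 992 ± 41.4 CPM and Rps3 at 811 ± 55.5 against 846 ± 56.1 CPM. The NRF2 antioxidant list and the p53 targets were not called by camera (adjusted p 0.115 and 0.282), while the mixed form of fry called the latter (adjusted p 0.0303). In edgeR 0 members of either passed over the list alone. At an unadjusted p under 0.05 there were 1 and 8, and DESeq2 called 0 and 2. Fth1 was at 5456 ± 236 against 5788 ± 441 CPM, Ftl1 at 2477 ± 193 against 2568 ± 416 CPM, Cdkn1a at 377 ± 13.2 against 353 ± 24.8 CPM and Btg2 at 227 ± 20.6 against 209 ± 9.05 CPM. For p53 targets the median was slightly negative, -0.006, and the mean and the camera direction positive.

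Other carbonic anhydrases and the transporters of acid and base showed no call as groups by camera. The mixed form of fry, which allows both directions, called both lists (adjusted p 0.0286 each). Camera gave an adjusted p of 0.518 for the carbonic anhydrases without Car4, 0.282 for acid-base transport, 0.457 for the V-ATPase subunits and 0.198 for the lysosome. The mitochondrial enzyme gene Car5b was the only carbonic anhydrase past the list alone (edgeR, Benjamini-Hochberg), at 31.7 ± 8.43 against 17.3 ± 1.48 CPM, and Car13 was at 4.58 ± 1.1 against 8.82 ± 3.99 CPM. Among acid-base transporters Gpr132 was higher and Slc9a2 and Slc9a9 lower over the list alone, and the most abundant, the proton channel gene Hvcn1 and the exchanger gene Slc9a4, were at 236 ± 12.6 against 223 ± 2.97 CPM and at 181 ± 12.7 against 159 ± 25.2 CPM. The acid-base list had a median of -0.03 and a mean of 0.04, with the camera direction down. No V-ATPase subunit passed over the list alone in edgeR, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2, and Atp6v1b2 was at 744 ± 50.5 against 719 ± 5.22 CPM. Of 43 lysosomal genes Ctsf was lower over the list alone, and the abundant Ctsd and Psap were at 8119 ± 539 against 9446 ± 1586 CPM and at 6558 ± 319 against 8210 ± 1364 CPM. Camera gave 0.992 for glycolysis and hypoxia, 0.88 for nuclear-encoded oxidative phosphorylation, 0.309 for mitochondrially encoded mRNAs, 0.745 for S phase, 0.467 for G2 and M phase, and 0.292 for iron handling as adjusted p. Over the list alone Tfrc and Steap3 of iron handling were higher and Cd163 lower. In edgeR 0 genes of the other lists passed so, with 8, 0, 2, 1 and 1 at an unadjusted p under 0.05 in the order given and 0 called by DESeq2 in each. The glycolysis list had a median of -0.003 and a mean of -0.006, with the camera direction up. The abundant glycolysis genes Aldoa and Pkm were at 1041 against 1023 CPM and 717 against 653 CPM, and Atp5b and Atp5a1 of oxidative phosphorylation at 857 against 879.7 CPM and 685 against 708 CPM. Values of the others were 4161 against 4330.3 CPM for mt-Co1, 1986 against 1933 CPM for mt-Cytb, 161 against 155 CPM for Pcna, 72 against 70.5 CPM for Mcm3, 139.6 against 163 CPM for Mki67 and 124 against 133 CPM for Smc4.

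Markers of other cells of the lung were examined as a measure of what the sort held. Those of B and plasma cells (16 of 18 above control), T and NK cells (17 of 20) and neutrophils (10 of 11) were higher by camera, with adjusted p of 0.000251, 0.000362 and 0.00906, and adjusted p of 0.534, 0.506 and 0.505 with an estimated correlation. Over the list alone Cd4, Cd8a and Il7r passed. In edgeR 0 passed of B and plasma cell markers (7 higher and 0 lower at an unadjusted p under 0.05, and 2 and 0 by DESeq2) and of neutrophil markers (3 higher and 1 lower at an unadjusted p under 0.05, and 1 and 0 by DESeq2). By camera the B and plasma cell call was lost with the stricter filter (adjusted p 0.271, against 6.47e-06 to 0.271 over the alternatives at the preset correlation) and the neutrophil call without control replicate 3 (adjusted p 0.0729, against 0.00758 to 0.0729 over the same alternatives). Medians in Cre libraries 1, 2 and 3 were 0.04, 0.36 and 0.80 for B and plasma cells, 0.12, 0.45 and 0.89 for T and NK cells, and 0.34, 0.75 and 0.34 for neutrophils. The most abundant T and NK cell markers, Il7r and Prf1, were at 0.721 ± 0.0487 against 7.6 ± 8.17 CPM and at 1.76 ± 0.893 against 1.26 ± 0.457 CPM, while Cd22, Cd37, Trem1 and Csf3r were at 159 against 161 CPM, 66 against 65.1 CPM, 223 against 184 CPM and 42.5 against 48.9 CPM. Camera did not call markers of classical monocytes (adjusted p 0.745), where Vcan and S100a4 were lower over the list alone and Gpx1 was at 714 against 753 CPM. For dendritic cells (camera adjusted p 0.166) Fscn1 and Ccl17 were higher and Clec9a lower over the list alone, with Sirpa at 2549 against 2432 CPM and Irf8 at 162 against 149.5 CPM. Of alveolar type 2 markers (camera adjusted p 0.238) Cdh1 was higher over the list alone, at 109 against 143 CPM, and Epcam lower, at 156, 129, 55.1 CPM in the controls and 35.4, 16, 22.6 CPM in the Cre libraries, with Abca3 at 121 against 119 CPM. Alveolar type 1 markers (camera adjusted p 0.741) had Cav1 at 62.9 against 59.6 CPM and Sema3e at 49.4 against 40.1 CPM. Of airway epithelium (camera adjusted p 0.518) Tppp3 was lower over the list alone and Scgb1a1 was at 5.26 against 6.1 CPM. Endothelial markers (camera adjusted p 0.707) had Vwf at 128 against 161 CPM and Calcrl at 47.4 against 51.3 CPM. Fibroblast and smooth muscle markers (camera adjusted p 0.828) had Col3a1 at 5.12 against 6.02 CPM and Col1a1 at 3.97 against 4.35 CPM. Erythroid and platelet markers (camera adjusted p 0.743) had Hbb-bs at 3.87 against 2.57 CPM and Pf4 at 0.887 against 2.17 CPM. In edgeR 0 type 1, endothelial, fibroblast and erythroid markers passed over the list alone, with 2, 1, 1 and 0 at an unadjusted p under 0.05 and 0, 1, 1 and 0 called by DESeq2. Medians over the control mean in Cre libraries 1, 2 and 3 were 0.63, -0.40 and -0.37 for endothelium, 0.68, -0.10 and 0.04 for type 2 cells, and 0.35, -0.31 and -0.05 for fibroblasts and smooth muscle, each highest in library 1. They were 0.23, -0.06 and -0.63 for erythroid cells and platelets, 0.39, -0.44 and -0.03 for eosinophils, basophils and mast cells, and 0.27, -0.04 and 0.45 for airway epithelium. Type 1 cells had 0.08, -0.02 and 0.04, classical monocytes 0.01, 0.19 and 0.06 and dendritic cells 0.05, 0.12 and 0.29. The airway median was 0.10 with the camera direction down, and the type 1 median was -0.004 and its mean 0.02, also with the direction down. Eosinophil, basophil and mast cell markers had 4 tested members, too few for camera. Over the list alone Siglecf was lower, at 708 ± 44.5 against 547 ± 71.7 CPM, and Ear6, whose reads can be shared with near-identical copies, higher, at 4.05 ± 1.05 against 9 ± 2.55 CPM. Both genes also belong to the list of alveolar macrophage identity, so their values need not reflect other cells.

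The neighbourhoods of the deleted gene and of the gene that drives the Cre were examined for local differences. Around Car4 no list member passed over the list alone in edgeR, with 1 at an unadjusted p under 0.05, 0 called by DESeq2, and a camera adjusted p of 0.745. The median was -0.05 and the mean 0.02, with the camera direction down. Ggnbp2 was at 184 ± 4.24 against 176 ± 3.93 CPM and Med13 at 106 ± 11.4 against 112 ± 9.12 CPM. Around Itgax camera gave an adjusted p of 0.707, with Itgax and Itgam higher and Armc5 lower over the list alone, a median of -0.01 and a mean of 0.10 with the direction up. Itgax was at 1693 ± 195 against 2438 ± 123 CPM (adjusted p 0.146, edgeR quasi-likelihood, Benjamini-Hochberg) and Hsd3b7 at 467 ± 8.67 against 400 ± 37.5 CPM. All 6 libraries came from females by their transcripts, with Xist at 463 ± 73 against 429 ± 41.9 CPM and at most 2 counts from Y-linked genes in any library.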

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

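The settings of glmQLFit other than the default were chosen only after seeing the data. Plcb4 was called under each alternative run, with log2 fold changes of 5.65 to 5.70. Car4 was lower under each, with log2 fold changes of -3.43 to -2.99 when 1 library was left out and adjusted p between 2.49e-28 and 0.0719 over the alternatives. It lost its call without control replicate 2 (-3.23, adjusted p 0.0549), with robust dispersions (-3.23, adjusted p 0.0719) and with these in the newer quasi-likelihood method (-3.23, adjusted p 0.0698), where 0 genes were called lower. Against 1 gene higher and 1 lower in edgeR, DESeq2 called 393 and 237, and the test without a filter on low counts 340 and 183. Leaving out 1 library gave between 1 and 249 genes higher and between 0 and 52 lower. With the replicate number as a block edgeR called 8 genes higher and 2 lower, Car4 and Tppp3 (adjusted p 0.0333). The higher genes were Plcb4, Arg1, Ccl24, Ighg1, Ighg2b, Rnase2a, Saa3 and Sel1l3. The deviations of libraries with equal numbers correlated at -0.01, -0.16 and 0.07, against -0.22 to 0.24 for unequal numbers. With 3 libraries per group these values cannot settle whether equal numbers share a day or batch, which is not stated in the sources used here. RLE, upper quartile and library-size scaling, limma-voom, the stricter filter, glmTreat, the other adjusted p thresholds, the newer quasi-likelihood method and leaving out genes of other cell types gave 1 gene in each direction. Of 17 gene lists 0 were called by camera with an estimated correlation and 0 by fry, and between 12 and 22 under the other alternatives. With the replicate block 15 were called, and the inflammatory cytokines and NF-kB targets (camera adjusted p 0.0705) and the cytosolic ribosomal proteins (0.0645) were not. Cytosolic ribosomal proteins turned direction without control replicate 2 (adjusted p 0.808) and Cre replicate 2 (0.969), with adjusted p from 5.07e-08 to 0.969 over the libraries left out. A term for sex was not run, as all libraries were of 1 sex. Of 152 genes named beside Car4, 136 kept 1 direction. The others spanned both signs, or reached 0, as libraries were left out: Atp6v1b2 (-0.10 to 0), Aldoa (-0.09 to 0.04), Itgb2 (-0.02 to 0.12), Gpx1 (-0.01 to 0.12), Ftl1 (-0.09 to 0.12), Fos (-0.25 to 0.08), Abca3 (-0.05 to 0.03), Cav1 (-0.17 to 0.03), Scgb1a1 (-0.28 to 0.45), Col3a1 (-0.06 to 0.88), Col1a1 (-0.26 to 0.80), Prf1 (-0.70 to 0.01), Cd22 (-0.02 to 0.07), Cd37 (-0.10 to 0.04), Hbb-bs (-1.06 to 0.39) and Xist (-0.20 to 0.02). The cause of these differences was not tested, and leaving out a library also lowers the number of samples. The depth of 53824475 counts or more puts the floor of 3 counts at 0.0557 CPM or less. Genes under the filter, with its minimum count of 10, were tested by DESeq2 and without a filter. Some of them were also tested when a library was left out, as these runs held 15498 to 15651 genes against 15147.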

Other observations

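Chosen only after the results were seen were the tests on the spread of the Cre libraries, and for Plcb4 both tests on paralogs, the test on other cells by their levels, and those on its neighbours and on chromosome 2. Transcripts outside the fixed lists that were nearly silent in the controls were present in the Cre libraries at unequal levels, and these genes too were chosen after their values were seen. Saa3, an acute-phase serum amyloid gene, had 0 counts in the controls and 1.03, 13, 12.1 CPM in Cre libraries 1, 2 and 3, at least 515-fold higher against a floor of 3 counts over the control group. The nonclassical MHC gene H2-M2 was at 0.3, 0.23, 0.09 CPM in the controls and 2.28, 27.7, 50.4 CPM in the Cre libraries. The immunoglobulin heavy chain gene Ighg2b was at 0.05, 0.03, 0.02 and 0.98, 21.8, 102 CPM, and Ighg1 had 1 count over the controls and 2685 over the Cre libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 4 genes had adjusted p of 0.146, 0.146, 0.153 and 0.146, and by DESeq2 1.56e-06, 7.52e-07, 1.01e-07 and 1.01e-05.

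The Cre libraries differed from each other: of the genes DESeq2 called higher 84.7% had their lowest Cre value in library 1, and of those it called lower 57% had their highest Cre value there. Fewer deleted cells in library 1 would leave more Car4 there, but it held 10.4% of the control mean, between the 12.2% and 9.4% of libraries 2 and 3, and its depth of 58914428 counts also lay between theirs. Interstitial macrophages in different shares may contribute, but the values are mixed and cannot decide. Their markers' medians differed by 1.03 (log2) between the highest and the lowest Cre library, and 16 of 19 markers were above control. Of their 2 most abundant markers and 2 genes of antigen presentation, Apoe and H2-Aa put the libraries in the same order, at 97.3, 250.3, 505 and at 27.9, 31.6, 54.5 CPM. Cd81 and Cd74 did not, at 189, 224, 168 and at 105, 101, 190.1 CPM, nor did the marker Cx3cr1, at 1.13, 1.89, 1.3 CPM. Cd163 was lower over the list alone, and H2-Aa was at 336, 201, 35.8 CPM in the controls. Other cells' markers differed too. T and NK cell medians differed by 0.77 and B and plasma cell medians by 0.76, in the order of the interstitial ones. Endothelial, alveolar type 2, and fibroblast and smooth muscle medians differed by 1.04, 0.78 and 0.66, each highest in library 1. Other cells cannot be told apart from a change within the macrophages, since what the sort, meant to leave such cells out, let through was not measured, and differences between mice of 1 genotype stay open, untested.

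Plcb4 rose to nearly 1 level in the 3 Cre libraries, with a highest-to-lowest ratio of 1.07. Reads shared with paralogs met the test as first written, since Plcb2 was higher by 45.7 CPM and Plcb4 by 27.3 CPM, but that test was replaced after its result because shared reads would follow the ratio of the paralog, and the largest ratio among Plcb1, Plcb2 and Plcb3, 1.17, argues against them. For cells of another type, a limit had been set beforehand. Finding 2 or fewer other genes at 10 or more times the control mean in each Cre library would have argued against them. The 8 found left this undecided. A later test, on the ground that 1 share of such cells would give like levels, was chosen after these values were seen. Of these 8 genes 0 stayed within 1.5 times across the Cre libraries. Cells whose other transcripts the macrophages already hold would escape this test, so it cannot decide and other cells stay open. An effect on the surrounding chromosome cannot be told apart from an effect on Plcb4, as only 3 genes within 1 Mb were tested, with log2 fold changes of -0.48 to 0.28 around a median of 0.18, all 3 with an unadjusted p under 0.05 in edgeR and 0 with an adjusted p under it, against 1 in DESeq2 (Plcb1, adjusted p 0.0263). Linked differences along chromosome 2, which a transgene or strain segment could bring, stay open with deletion of Car4: at unadjusted p limits of 5e-04, 0.001 and 0.005 the chromosome held 8 of 43, 11 of 98 and 30 of 406 genes against 3.4, 7.7 and 31.9 expected (Fisher's exact p 0.0174, 0.254 and 0.78, the smallest 0.0521 after Benjamini-Hochberg adjustment over the limits). Plcb4 itself is counted among these genes, and the p-values are not adjusted for choosing its chromosome after the result. Among the 10 genes of smallest p named on each side, Plcb4, Sestd1, Fmnl2, Slc30a4 and Thbd, all higher, and Galnt3, lower, lie on chromosome 2. Their starts lie between 52857860 and 148404466.

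The cholesterol synthesis list was higher in each Cre library. Scaling does not account for it, since its lowest median log2 fold change under RLE, upper quartile and library-size scaling was 0.43. Nor do GC content and transcript length, as the median lay at the 100th percentile of 10000 random lists matched on these and on expression, whose highest was 0.10. A single library does not carry it, the lowest of the 3 Cre library medians being 0.32. A change in the sterol pathway after deletion of Car4 may be a candidate explanation, as an untested hypothesis: the call of the list is lost with an estimated correlation (camera adjusted p 0.505), and its exact permutation p is 0.1. A difference in the cells sorted and an effect of the Cre transgene remain open.

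The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2 genes, and 1 split of 10, the real one, gave as many; the highest of the others gave 1. For gene lists the real split called 17, 4 of the 10 splits gave as many, and the highest other gave 27, in the split that exchanges control library 1 and Cre library 1 and keeps the other libraries of each genotype together. Of the 17 lists 12 had their largest mean difference in the real split, at an exact permutation p of 0.1, the smallest that 10 splits can give, while MHC class II, immediate early, ribosomal protein, neutrophil, and B and plasma cell genes had a larger one in another split.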
